A study of Bubalus bubalis with 12 samples.

How the data were processed

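Spermatozoa of 6 buffalo bulls, 3 high-fertile (HF2, HF3 and HF5) and 3 subfertile (SF1, SF4 and SF5), were profiled for H3K4me2 and H3K27me3 on 12 Agilent arrays, 1 per bull and mark. Per the labels, chromatin was cross-linked and digested with micrococcal nuclease, precipitated with antibodies to either mark, and the recovered and input DNA were blunted, ligated to linkers, amplified by linker-mediated PCR and labelled, ChIP in Cy5 and input in Cy3 on every array, with no dye swap. The intensity values per spot and colour were made by the authors with Agilent Feature Extraction 10.7, as the submitters' processing notes state (10.7.3.1 per the file headers), which subtracted background, removed spatial trends and normalized the dyes within each array. The same deposited files hold a log10 ratio of the 2 colours and quality flags of 0 and 1 per spot, per the file headers. The deposited value table holds log2 ratios of ChIP over input, which the authors had corrected for a dependence on brightness, as read from the values; the method is not stated. Its 177439 probes were checked against the scanner files: its columns correlated with the unadjusted log2 ratios at r from 0.74 to 0.994 with slopes from 0.56 to 1.03, and with ratios after within-array loess at 0.982 to 0.995, which settled the scale and the direction, ChIP over input. Its column medians for H3K4me2 were 0 in HF2, 0.1 in HF3, -0.11 in HF5, 0.04 in SF1, -0.01 in SF4 and -0.13 in SF5, and for H3K27me3 -0.01, 0.09, -0.07, 0.03, -0.01 and -0.02 in the same order, so no column but the first was centred exactly on 0.

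Values used here were log2 ratios of the processed Cy5 over the processed Cy3 signal. Of 177440 non-control probes (3440 control spots left out), 177372 were kept whose input signal was well above background on at least 6 of 12 arrays. Spots marked as outliers in either colour, 13 to 546 per array, were set missing, and saturated spots (151 to 558 per array in the ChIP colour) stayed in. Each array was centred on the median of its kept probes. A gene's value was the mean of its kept probes, at least 2, which gave 6805 genes out of 9328 symbols, 2522 symbols having 1 probe; 320 of the genes carry locus identifiers and 68 have probes on several chromosomes, and these are given only in counts. Probes were designed on cattle sequence, and positions are those of HGSC Btau_3.1 per the file headers; 7834 symbols matched the buffalo RefSeq table by name. Input signal was well above background at 97.1% to 99.9% of probes per array and ChIP signal at 93.9% to 99.98%. The half-width of the 95% confidence interval, 1.20 and 1.10 log2 units in the median gene, gives the precision that 3 bulls per group allow.

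Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg at 0.05), for genes and, on the 175796 probes with values on all 12 arrays, for probes. The comparisons were high-fertile with subfertile bulls for each mark on its 6 arrays, the difference of that difference between marks and H3K4me2 with H3K27me3 on all 12 arrays, and the mean log2 ratio of each mark against 0. The same bull number within a fertility group was read as the same animal, because the 2 arrays of that number lie on the same slide and their input signals, as deviations from the mean of the 6 bulls, correlated across genes at r of at least 0.939 (mean 0.966), while those of different bulls reached at most 0.193; number 5 in both groups stands for different bulls. Bulls as replicate blocks entered as an alternative. Slide 4 held HF5 and SF1, and every other slide 1 bull, so slide and bull cannot be told apart elsewhere. Lists were tested with limma's camera at an inter-gene correlation of 0.01, and with an estimated correlation: protamines and transition proteins, spermatogenesis, sperm flagellum and motility, acrosome and fertilization, testis-specific glycolysis isozymes, early embryo and pluripotency, HOX clusters, developmental transcription factors, developmental signalling, imprinted genes, ribosomal proteins, other housekeeping, chromatin modifiers, steroid and gonadotropin signalling, apoptosis, olfactory receptors (2 on the array, 0 with enough probes), and leukocyte, epithelial and somatic testis markers. The protamine list had 1 gene with enough probes, so camera ran on 17 lists.

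Comparisons, lists, the naming rule and most alternatives were set before the data were examined. Named genes were, per fertility comparison, the 10 largest differences in each direction past an adjusted p of 0.05 with no overlap of the groups, filled with the smallest unadjusted p under the same condition where too few passed. For enrichment and the mark comparison they were the 10 highest and 10 lowest past 0.05 with one sign in all 6 bulls. In each list they were the 2 members of smallest p, of which some are not reported here. TNP1, HOXA and HOXD genes, IGF2 and a few others could be named in any case. Genes named in the mark comparison were chosen after their values were seen.

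The fits were tested on simulated data with the residual spread of these genes and arrays, 200 changed genes in each of 5 runs of 6805 genes. Every run mixed changes of 1, 2, 3 and 4 log2 units. Large changes ease the correction for the small ones, so recovery of small changes without large ones beside them was not measured and may be lower. Between fertility groups 1.6% of H3K4me2 changes of 1 log2 unit, 28.8% of 2, 56.4% of 3 and 75.2% of 4 were recovered, with 4 false calls over the runs. For H3K27me3 these were 0.8%, 35.2%, 62.8% and 78.4%, with 11 false calls. Enrichment of 1 log2 unit was recovered in 38.4% of genes for H3K4me2 and 47.6% for H3K27me3, and of 2 units in 80.8% and 84.4%, with 24 and 21 false calls. Alternatives were within-array loess (span 0.3), normexp background correction (offset 50), quantile normalization, the deposited table, other filters and summaries, the Cy5 signal alone, bull or position in the model, and leaving out each bull. Chosen after seeing the data were removal of the GC trend, leaving out HF5 and SF5 together, slide as a random block on all 12 arrays, alternatives for array agreement, and loess for regions without a symbol.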

Results

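The series profiled 2 histone marks in spermatozoa from cryopreserved semen of water buffalo (Bubalus bubalis) bulls: histone H3 dimethylated at lysine 4 (H3K4me2), which lies at promoters of active or poised genes, and histone H3 trimethylated at lysine 27 (H3K27me3), which Polycomb complexes place at silenced genes. The bulls formed a high-fertile group of 3 (HF2, HF3 and HF5) and a subfertile group of 3 (SF1, SF4 and SF5). Each bull gave 1 ChIP-on-chip array per mark, 12 arrays in all, with immunoprecipitated DNA in Cy5 and input DNA of the same bull in Cy3. Each value is the log2 ratio of ChIP over input, relative to the median probe of its array, so it ranks genes within an array and gives no absolute level. The array held 177440 non-control probes of 60 bases, of which 160708 lay in CpG islands, 13422 in promoters and 3310 in coding sequence by the array's own annotation on the cattle build HGSC Btau_3.1. The median signal per array ranged from 321 to 479 in the input channel and from 356 to 1360 in the ChIP channel. The 2 lowest ChIP medians for H3K4me2 were 588 in HF5 and 356 in SF5, 1 bull of each group, and on these arrays probes of at least 53.3% G and C exceeded those of at most 46.7% by 0.90 and 1.02 log2 units. The number of arrays limited the precision: the median 95% confidence interval of a gene's group difference reached 1.20 log2 units to either side for H3K4me2 and 1.10 for H3K27me3.

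Log2 ratios over each bull's own input went with the bull more than with the mark. The log2 ratios of the 6805 genes correlated between the H3K4me2 and H3K27me3 arrays of one bull with Pearson r of 0.65 in HF2, 0.80 in HF3, 0.44 in HF5, 0.86 in SF1, 0.40 in SF4 and 0.25 in SF5, a mean of 0.567. Arrays of the same mark from different bulls had a median r of 0.0051 over 30 pairs. Over all 60 pairs of arrays from different bulls, r ranged from -0.13 to 0.27. An exact one-sided permutation test over the 720 ways of pairing the 6 H3K4me2 with the 6 H3K27me3 arrays gave p = 0.00139 for the same-bull mean, the smallest that these pairings can give. With the ChIP signals set against the mean input of the 6 bulls, the same-bull mean was 0.297 (HF2 0.46, HF3 0.18, HF5 0.38, SF1 0.47, SF4 0.19 and SF5 0.10), against a median of 0.139 for different bulls and marks. These correlations run across genes, which are not independent replicates, and both arrays of a bull lay on one slide and were set against input DNA of that bull.

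**Figure D1:**
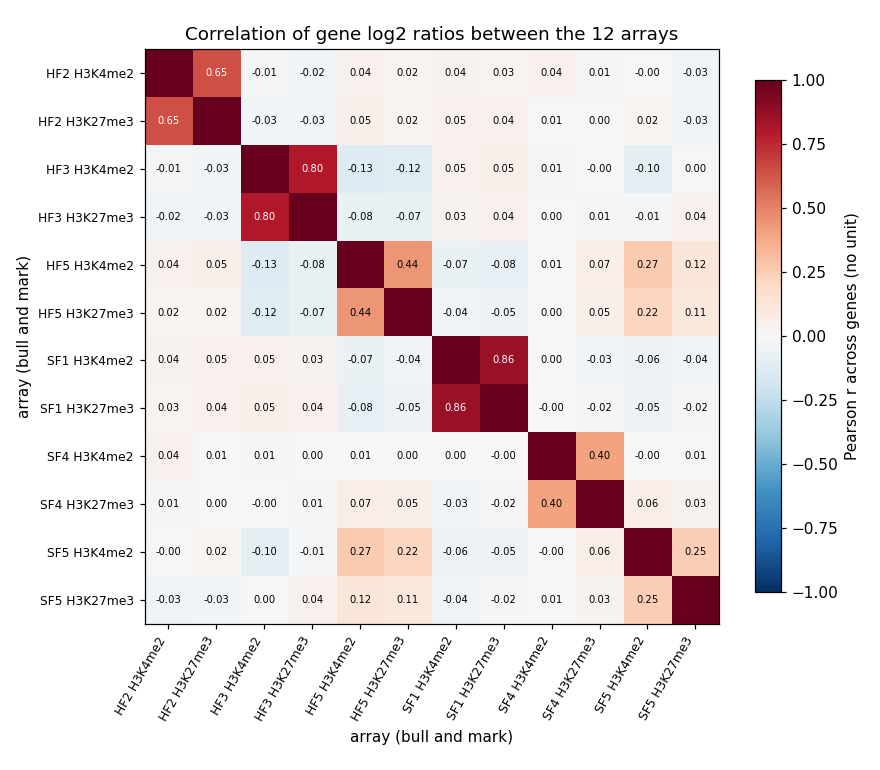
Pearson r (no unit) across 6805 genes between every pair of the 12 arrays, ordered by bull, with both axes naming bull and mark. Pairs from one bull lie between 0.25 and 0.86, and pairs from different bulls between -0.13 and 0.27.

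The comparison the series names is that of high-fertile with subfertile bulls, made first for H3K4me2 over 6805 genes. KAT7, which encodes a histone H3 and H4 acetyltransferase, had the smallest unadjusted p among genes with the lower values in high-fertile bulls: its 28 probes on chromosome 19 (38038440 to 38043195), 27 of them in CpG islands, averaged -0.56 ± 0.22 in high-fertile and 1.38 ± 0.56 in subfertile bulls (log2, mean ± SD, n = 3 bulls each here and in what follows). ZNF192, a zinc finger transcription factor gene with 2 CpG island probes on chromosome 23 (30612110 to 30612203), stood the other way, at 1.18 ± 0.68 against -1.71 ± 0.75, a difference of 2.89 with a 95% confidence interval of 1.63 to 4.15. OXSR1, a kinase of osmotic and oxidative stress signalling with 53 probes on chromosome 22 (11753244 to 11754219), averaged 0.79 ± 0.63 in high-fertile and -0.83 ± 0.05 in subfertile bulls. None of these genes passed the correction: limma called 0 of 6805 genes at an adjusted p of 0.05, with a lowest adjusted p of 1.00, an unadjusted p of 0.000630 for ZNF192 and of 0.00221 for KAT7.

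The 20 genes named for H3K4me2 were those of smallest unadjusted p whose 3 high-fertile arrays all lay on one side of the 3 subfertile arrays, 10 in each direction. TXNDC5, a protein disulphide isomerase of the endoplasmic reticulum, averaged 1.77 ± 0.96 in high-fertile and -0.82 ± 0.70 in subfertile bulls, and LMAN2L, a lectin of the secretory pathway, differed by 1.65. SERP1, a stress-associated protein of the endoplasmic reticulum, had the opposite sign, -1.23 ± 1.19 against 1.02 ± 0.48, as did DNAJB9, a co-chaperone of the same compartment, with -0.92 ± 0.55 against 0.65 ± 0.39 over 3 promoter probes. KPNB1, the importin that carries proteins into the nucleus, averaged 0.53 ± 0.57 against -1.18 ± 0.38 over 10 probes. DIABLO, a mitochondrial protein that promotes apoptosis, averaged -1.30 ± 0.72 against 0.45 ± 0.49, and PATZ1, a zinc finger regulator of transcription, -0.44 ± 0.36 against 0.86 ± 0.04 over 34 probes. The remaining genes with higher values in high-fertile bulls were RUNDC3B (3.53), ZNF35 (3.14), ASB8 (2.21), the beta-defensin gene DEFB123 (1.97) and the RING finger gene RNF121 (1.58). Those with lower values were TMEM177 (-2.75), C1QTNF6 (-2.14), the actin-bundling fascin gene FSCN2 (-2.06), the splicing factor gene CWC25 (-1.75) and the mitochondrial carrier gene SLC25A40 (-1.67), whose difference was 0.27 when the Cy5 signal was taken alone. Across all genes, 198 (2.91%) had an unadjusted p under 0.05 in limma, where chance gives a share of 0.05. Of these 115 were higher and 83 lower in high-fertile bulls, a balance that moved with single bulls (174 of 242 higher without HF5, 85 of 199 without SF5, 105 of 224 without SF4, 100 of 202 without HF3). In 448 genes (6.58%) the bulls of the groups did not overlap, where chance gives 10%. Of 175796 probes, limma called 0, and 5295 (3.01%) had an unadjusted p under 0.05, 2894 higher and 2401 lower. Of such probes 5086 of 6935 were higher without HF5, 1927 of 5927 without SF5, and 4250 of 8163 without both. Within slide 4, the only slide that held a bull of each group, the HF5 minus SF1 difference correlated across genes at -0.23 with the difference among the other 4 bulls. HF5 and SF5 enter these differences with opposite signs. Their H3K4me2 arrays had the highest r between bulls, 0.27, which adds to the negative value. HF3 and HF5 enter with the same sign and had the lowest r between bulls, -0.13, which adds to it too. The negative value thus rests in part on single pairs of arrays and cannot by itself show a reversed fertility difference.

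**Figure D2:**
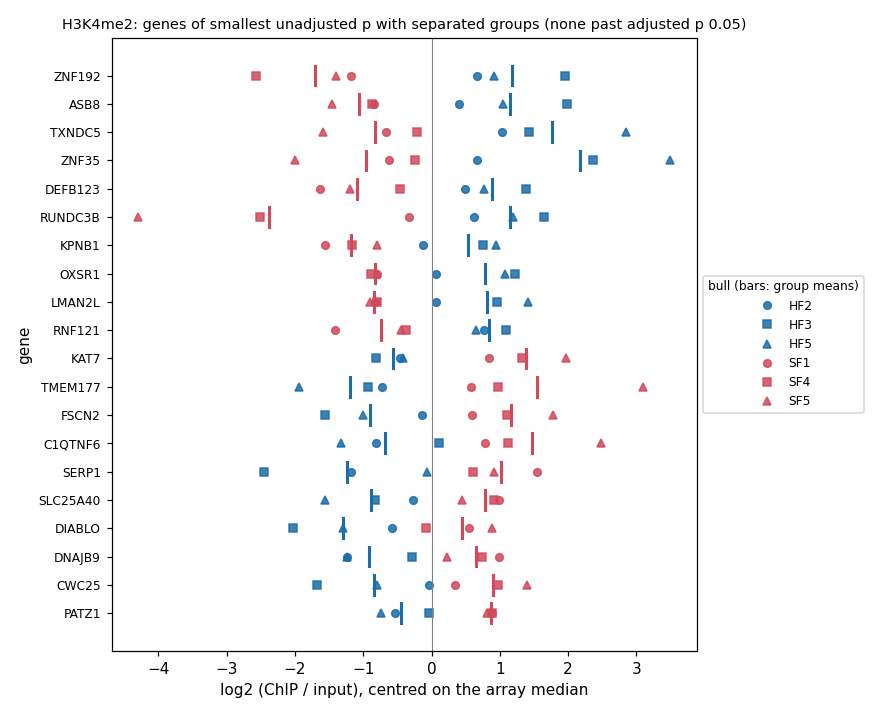
H3K4me2 log2 ratio of ChIP over input (horizontal axis, centred on the array median) for each of the 20 named genes (vertical axis), with a point per bull, blue for the 3 high-fertile and red for the 3 subfertile bulls, and bars for group means. None passed an adjusted p of 0.05, and SLC25A40 took the other sign when the Cy5 signal was used alone.

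Gene lists fixed beforehand gave no call for H3K4me2 between fertility groups. In each list 0 members passed the correction over all genes and 0 when adjusted over the list alone. Of the 51 measured ribosomal protein genes 27 were higher and 24 lower in high-fertile bulls; RPS19 (0.76 ± 0.99 against -0.81 ± 0.28) and RPS26 (1.37 ± 0.97 against 0.00 ± 0.43) had the smallest p. Of the 19 genes of the sperm flagellum and motility 11 were higher and 8 lower, and the tektin gene TEKT3 (-0.55 ± 0.65 against 0.72 ± 0.59) and the fibrous sheath gene ROPN1L (-0.86 ± 0.96 against 1.02 ± 1.47) were among those lower. HOXD4 (difference 1.95) and HOXD12 (0.92), homeobox genes of body axis patterning, had the smallest p of 22 HOX cluster genes, of which 8 were higher and 14 lower. Among regulators of development, the signalling gene WNT6 averaged 0.84 ± 0.86 against -0.74 ± 0.18, and the transcription factor gene PITX1 differed by -0.81. ELF5, a regulator of trophoblast, differed by 1.04 and the maternal gene ZAR1 by -1.20. Among chromatin modifiers UHRF1, which guides maintenance DNA methylation, differed by 1.72 and ASH2L, a subunit of H3K4 methyltransferases, by -0.86. TNP1, a transition protein that replaces histones before protamines do, was the only measured member of its list, at -0.28 ± 0.48 against 0.20 ± 0.15. The germ cell genes GFRA1 (0.76) and MAEL (-0.52), the acrosomal PRSS37 (-1.09), the apoptosis gene BCL2L11 (-0.66), the splicing gene SRSF1 (1.51) and the imprinted MEG3 (-1.13) were among the 2 members of smallest p in their lists. Within slide 4 the difference was 0.25 for MAEL, 0.50 for MEG3 and 0.13 for TNP1.

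Markers of other cells were measured in the same way for H3K4me2. HSD3B1, a steroid-producing enzyme of Leydig cells that stands in the lists of somatic testis markers and of steroid signalling, averaged -0.89 ± 0.62 in high-fertile and 0.60 ± 0.58 in subfertile bulls. The macrophage receptor gene CSF1R differed by -1.08 and the epithelial claudin gene CLDN4 by -1.12. The group difference of the list medians, high-fertile minus subfertile, was 0.18 for epithelial, 0.06 for leukocyte and 0.05 for somatic testis markers. It was 0.14 for the flagellum, 0.13 for ribosomal proteins, 0.12 for developmental signalling, 0.11 for acrosome, for HOX clusters and for early embryo genes, 0.07 for apoptosis and 0.01 for developmental transcription factors. It was -0.00 for other housekeeping genes, -0.07 for chromatin modifiers, -0.09 for imprinted genes, -0.10 for spermatogenesis, -0.22 for steroid signalling, -0.26 for testis-specific glycolysis isozymes and -0.48 for TNP1 alone. The bulls' medians separated fully, with an exact permutation p = 0.1, for early embryo genes, for steroid signalling and for somatic testis markers, whose sign turned under loess. Limma's camera test called 0 of 17 lists, with 0 at an unadjusted p under 0.05, a lowest adjusted p of 0.920, and a lowest adjusted p = 0.941 with an estimated correlation. The difference of list medians, the median gene difference, the mean gene difference and the test did not all have one sign for HOX clusters, acrosome, apoptosis, developmental signalling, developmental transcription factors, epithelial, leukocyte and somatic testis markers and steroid signalling. The values for HOX clusters, acrosome, apoptosis and somatic testis markers were negative under within-array loess and in the deposited table. Leaving out bulls turned the sign for spermatogenesis (0.07 without SF5), chromatin modifiers (0.04 without SF1), leukocyte markers (-0.02 without HF2), housekeeping genes (0.12 without HF5), developmental transcription factors (-0.04 without HF5 and SF5) and imprinted genes (0.08 without HF5 and SF5). Steroid signalling stood at -0.11 without HF5 and -0.02 under loess. Over 11 alternatives the difference ran from 0.04 to 0.31 for epithelial markers, whose high-fertile medians were -0.09 in HF2, 0.45 in HF3 and 0.16 in HF5. It ran from 0.06 to 0.27 for the flagellum, from 0.02 to 0.18 for ribosomal proteins and from -0.09 to 0.25 for acrosome genes.

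For H3K27me3 the same comparison ranked other genes first. OXA1L, which inserts proteins into the inner mitochondrial membrane, averaged -2.27 ± 0.80 in high-fertile and 1.10 ± 0.31 in subfertile bulls over 3 CpG island probes on chromosome 10 (22340942 to 22341037), a difference of -3.37 with a 95% confidence interval of -4.48 to -2.26. CCNA2, the cyclin of S phase and mitosis, with 6 probes on chromosome 6 (3380995 to 3381080), averaged 0.93 ± 0.34 against -0.99 ± 0.18. EIF3D, a translation initiation factor subunit with 38 probes on chromosome 5 (80567871 to 80568182), averaged -0.65 ± 0.40 against 1.18 ± 0.41. Limma called 0 of 6805 genes at an adjusted p of 0.05: OXA1L had an unadjusted p of 0.000104 and an adjusted p of 0.705, with all 3 high-fertile bulls below all 3 subfertile bulls, and CCNA2 an unadjusted p of 0.000792.

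The 20 genes named for H3K27me3 were chosen in the same way. GINS1, part of the helicase that unwinds replicating DNA, averaged -1.50 ± 0.28 in high-fertile and 0.21 ± 0.44 in subfertile bulls, and CSNK2B, the regulatory subunit of casein kinase 2, -0.72 ± 0.78 against 1.23 ± 0.27. SMYD1, a histone methyltransferase of muscle, differed by -2.66, and LCORL, a transcription factor gene linked to body size in cattle, by -1.42. DNAJB9, named also for H3K4me2, averaged -0.66 ± 0.59 against 0.95 ± 0.13 on the same 3 probes. The microtubule-binding protein gene EML5 differed by 2.04 over 12 probes and TCTEX1D1, which encodes a dynein light chain relative, averaged 0.81 ± 0.02 against -0.81 ± 0.33. HHATL averaged 1.37 ± 1.08 against -1.23 ± 0.30, and C1QTNF1 1.19 ± 0.72 against -0.91 ± 0.58 over 30 probes. The remaining genes with higher values in high-fertile bulls were RUNDC3A (2.82), the carbonic anhydrase relative CA10 (2.50), the RNA-binding protein gene RBMS1 (2.06), FAM105B (1.94) and the pterin dehydratase gene PCBD1 (1.56). Those with lower values were NGDN (-1.59, 29 probes), the serpin gene SERPINI1 (-1.46) and FAM198B (-1.37). Across all genes 277 (4.07%) had an unadjusted p under 0.05 in limma, where chance gives a share of 0.05. Of these 152 were higher and 125 lower (196 of 391 higher without HF2, 145 of 328 without HF3, 199 of 339 without HF5, 165 of 261 without SF1, 107 of 242 without SF4, 116 of 248 without SF5). In 583 genes (8.57%) the groups did not overlap, where chance gives 10%. Of 175796 probes, limma called 0, and 7584 (4.31%) had an unadjusted p under 0.05, 3905 higher and 3679 lower. Of such probes 5432 of 11363 were higher without HF2, 5551 of 9018 without HF5 and 2757 of 6874 without SF5. Within slide 4 the HF5 minus SF1 difference correlated across genes at -0.13 with that among the other 4 bulls. Here too HF5 and SF5, at r 0.11 for this mark, enter with opposite signs, and HF3 and HF5, at r -0.071, with the same sign.

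**Figure D3:**
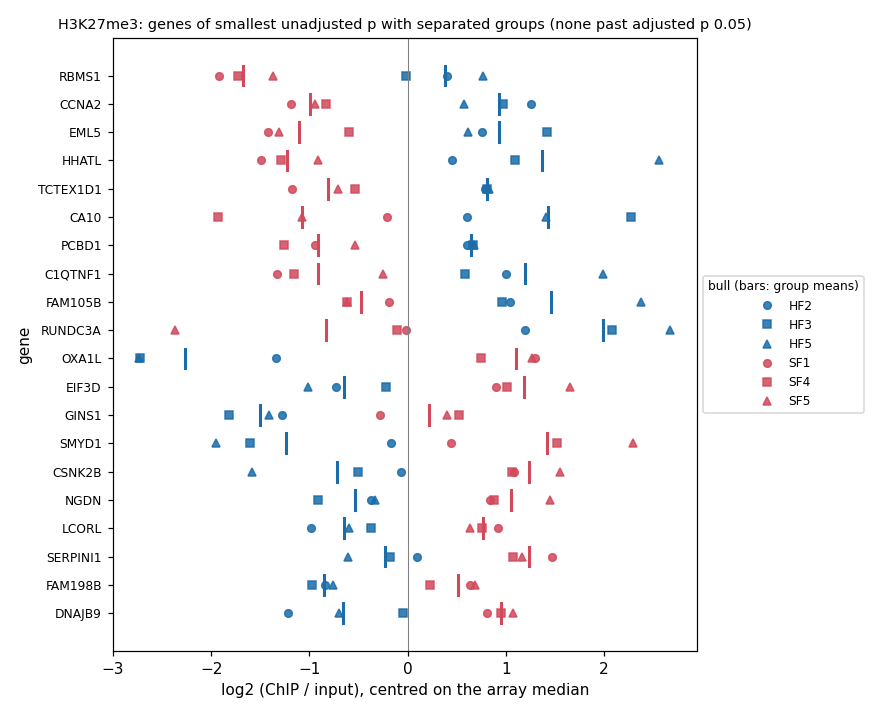
H3K27me3 log2 ratio of ChIP over input (horizontal axis, centred on the array median) for each of the 20 named genes (vertical axis), with a point per bull, blue for the 3 high-fertile and red for the 3 subfertile bulls, and bars for group means. OXA1L had the largest difference, -3.37, and none passed an adjusted p of 0.05.

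Among the fixed lists, spermatogenesis genes had the largest difference in H3K27me3 list median in size. The 13 measured members averaged a list median of 0.24 ± 0.13 in high-fertile and -0.08 ± 0.09 in subfertile bulls, a difference of 0.32, with 9 members higher and 4 lower; the difference stayed between 0.25 and 0.39 over 11 alternatives. The exact two-sided permutation test of these bull medians gave p = 0.1, the smallest that 3 bulls against 3 can give. Ribosomal proteins (0.08) and epithelial markers, which stand for another cell type (-0.25), separated as fully, with the same exact p. Over the 11 alternatives these differences ran from 0.03 to 0.09 and from -0.36 to -0.05. Most of these alternatives left out bulls, which cannot turn the sign where the bulls' medians separate fully. For these lists the ranges are therefore not a measure of robustness. For spermatogenesis genes limma's camera gave an unadjusted p of 0.0403 and an adjusted p of 0.684. With an estimated correlation the lowest adjusted p was 0.944, so the list failed the correction. GFRA1, the receptor that maintains spermatogonial stem cells, averaged 0.84 ± 0.90 against -0.15 ± 0.45, and KIT, the receptor of differentiating spermatogonia, 0.29 ± 0.73 against -0.63 ± 0.66. Acrosome and fertilization genes had a difference of -0.25 in list median, 5 of 16 higher and 11 lower, with a camera p of 0.0841 and an adjusted p of 0.715. It ranged from -0.45 to -0.03 over 11 alternatives and was -0.04 without HF5. The sperm ADAM gene ADAM32 differed by -1.40 and PRSS37 by -0.58.

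The other lists gave no call for H3K27me3 either: camera called 0 of 17 lists, 1 had an unadjusted p under 0.05, and in each list 0 members passed over all genes and 0 when adjusted over the list alone. HOXD12, with 60 probes, averaged 0.74 ± 0.99 in high-fertile and -0.81 ± 0.69 in subfertile bulls, and HOXB9 differed by 0.72; of 22 HOX cluster genes 11 were higher and 11 lower. The neural transcription factor gene NEUROD1 averaged 0.74 ± 0.16 against -0.14 ± 0.16 and MSX2 differed by 1.08, among 65 developmental transcription factors of which 35 were higher. RNF2, the Polycomb ubiquitin ligase of histone H2A, averaged -0.26 ± 0.26 against 0.78 ± 0.26, and UHRF1 differed by 1.15. Ribosomal RPS21 (-1.20) and RPSA (-0.76), imprinted BLCAP (-1.19) and UBE3A (-1.20), embryonic CDX2 (-0.73) and ZAR1 (-0.72), the glycolytic ENO1 (-1.08), testis-specific LDHC (-0.76) and the signalling gene GREM1 (-0.58) had lower values in high-fertile bulls. The apoptosis gene MCL1 (0.71), the steroid reductase gene SRD5A2 (0.96) and the radial spoke gene RSPH9 (1.01) had higher ones. TNP1 averaged -0.43 ± 0.29 against -0.31 ± 0.60; its difference of -0.13 was 0.15 without SF1 and 0.47 with the Cy5 signal alone. Of the cell type markers, the endothelial VWF differed by -1.72, the neutrophil receptor gene CXCR2 by 0.84, and the epithelial ESRP1 by 0.57 and KRT18 by -0.58.

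The differences of H3K27me3 list medians, high-fertile minus subfertile, were 0.15 for steroid signalling (0.06 to 0.27 over 11 alternatives), 0.09 for HOX clusters and apoptosis, 0.08 for chromatin modifiers and ribosomal proteins, and 0.02 for developmental transcription factors. They were -0.03 for developmental signalling and early embryo genes, -0.05 for imprinted genes, -0.07 for the flagellum, -0.12 for other housekeeping genes and -0.23 for testis-specific glycolysis isozymes. Of the cell type markers they were -0.02 for somatic testis, -0.07 for leukocyte and -0.25 for epithelial markers. The difference of list medians, the median gene difference, the mean gene difference and the test did not all have one sign for apoptosis, chromatin modifiers, early embryo, imprinted, leukocyte, ribosomal and flagellum genes. Under normexp background correction, loess or the deposited table the sign turned for apoptosis, chromatin modifiers, early embryo genes, leukocyte markers, somatic testis markers, developmental transcription factors and the flagellum. Leaving out bulls turned it also for testis-specific glycolysis isozymes (0.16 without HF3), HOX clusters (-0.02 without SF4), developmental signalling (0.01 without HF5 and SF5) and imprinted genes (0.01 without HF5 and SF5).

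**Figure D4:**
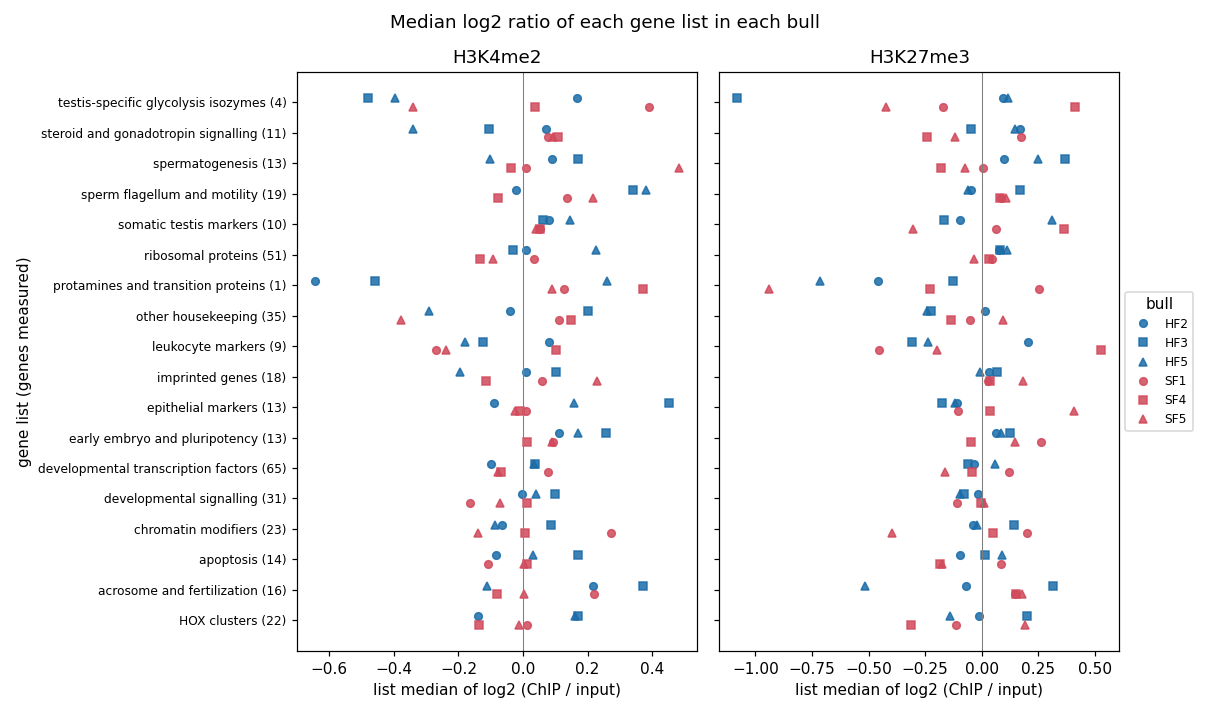
Median log2 ratio of ChIP over input (horizontal axes) of each gene list (vertical axis, measured genes in brackets) in each of the 6 bulls, H3K4me2 on the left and H3K27me3 on the right, blue for high-fertile and red for subfertile bulls. For H3K27me3 the 3 high-fertile bulls all lie above the 3 subfertile bulls for spermatogenesis and ribosomal proteins and all lie below them for epithelial markers, and none of these lists passed the correction; signs of the smaller medians, and of the glycolysis isozymes, turn with the normalization or with single bulls.

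Whether the fertility difference itself differed between the marks was tested over all 12 arrays. Of the genes named, DNAJB9 had differences of -1.57 for H3K4me2 and -1.60 for H3K27me3, HOXD12 of 0.92 and 1.54, GFRA1 of 0.76 and 0.98, ZAR1 of -1.20 and -0.72, UHRF1 of 1.72 and 1.15, and PRSS37 of -1.09 and -0.58. Limma called 0 of 6805 genes for the difference between marks. In this fit an unadjusted p under 0.05 was found for 45 genes (0.661%). The fit took the 2 arrays of a bull as independent, although they correlated. This widened its errors (median standard error 0.732, against 0.490 with the bull as a replicate block), so its share cannot be set against a chance share of 0.05. With that block limma gave an unadjusted p under 0.05 for 268 genes (3.94%), where chance gives a share of 0.05, at a lowest adjusted p of 0.974. The unblocked count of 45 was 71 without SF1, 17 without SF5 and 15 without HF5 and SF5. Spermatogenesis genes had the smallest camera p of 17 lists for this difference, 0.0256, at an adjusted p of 0.435. That test took the 2 arrays of a bull as independent. The differences in the 2 marks correlated across genes at r = 0.46, and 82 genes were separated in both marks in the same direction and 2 in opposite directions. The other 9 ways of splitting the 6 bulls into 3 and 3 gave r from 0.47 to 0.61 and 92 to 237 genes separated in both marks in the same direction.

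Enrichment over input asked where each mark lay in sperm of all 6 bulls, relative to the median probe. For H3K4me2, the ribosomal protein gene RPL9 averaged 0.97 ± 0.83 (log2, mean ± SD over 6 bulls) and RPS3A -0.95 ± 0.67, and ASH2L averaged 0.65 ± 0.53. TEKT4, a tektin of the flagellum, averaged 0.48 ± 0.36, the intermediate filament gene VIM 0.40 ± 0.25 and IZUMO4, of the sperm-egg fusion family, 0.38 ± 0.36, each above 0 in 6 of 6 bulls. HOXB7 averaged -0.38 ± 0.20 over 53 probes and the granulosa cell transcription factor gene FOXL2 -0.66 ± 0.88, each below 0 in 6 of 6 bulls. The head organizer gene OTX2 averaged -0.56 ± 0.42, the elongation factor gene EEF2 -0.60 ± 0.49, the splicing gene SRSF3 -0.57 ± 0.49, HOXA5 -0.43 ± 0.47 over 187 probes, and the germ cell gene MAEL 0.46 ± 0.44. TNP1 stood at -0.04 ± 0.41, and took positive values of up to 0.32 under loess, in the deposited table and with the GC trend removed. None passed: limma called 0 of 6805 genes, with a lowest adjusted p of 0.933. An unadjusted p under 0.05 was found for 302 genes (4.44%), where chance gives a share of 0.05. Of these 123 lay above and 179 below 0 (67 of 316 above without centring, 0 of 107 with trend and robust moderation, 216 of 343 without HF5 and SF5). Of all genes 244 (3.59%) had one sign in all 6 bulls, where chance gives 3.125%.

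For H3K27me3, LCP2, an adaptor of T cell receptor signalling, averaged -0.83 ± 0.34 over 2 probes, below 0 in 6 of 6 bulls. Its adjusted p was 0.920 over all genes, and it was the 1 member among 9 leukocyte markers past 0.05 when adjusted over the list alone. WNT3, a ligand of primitive streak formation, averaged -0.71 ± 0.44 over 60 probes and CHD1, a chromatin remodeller that binds methylated H3K4, -0.45 ± 0.34, each below 0 in 6 of 6 bulls. COX5A, of the respiratory chain, averaged -2.40 ± 1.91 and the smooth muscle myosin gene MYH11 -0.61 ± 0.41. The proteasome gene PSMA2 averaged 0.83 ± 0.51, RPL17 0.92 ± 0.80, RPL9 0.61 ± 0.34, the survival gene MCL1 0.51 ± 0.56 and the follicle-stimulating hormone receptor gene FSHR 1.53 ± 2.10. HOXA5 averaged -0.36 ± 0.35 and HOXA9 0.30 ± 0.44, and TNP1 -0.37 ± 0.43. Limma called 0 of 6805 genes, with a lowest adjusted p of 0.872. An unadjusted p under 0.05 was found for 360 genes (5.29%), where chance gives a share of 0.05. Of these 134 lay above and 226 below 0 (164 of 327 above under loess, 174 of 336 in the deposited table, 119 of 260 without SF5, 170 of 310 without HF5 and SF5). Of all genes 239 (3.51%) had one sign in all 6 bulls, where chance gives 3.125%.

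By list, early embryo and pluripotency genes had the smallest p for H3K27me3 enrichment. The mean of the 6 bulls' list medians was 0.11 over 13 members, above 0 in 5 of 6 bulls and between 0.07 and 0.14 over 11 alternatives, with a camera p of 0.0195, an adjusted p of 0.331, and an adjusted p = 0.9902 with an estimated correlation. For H3K4me2 the same list stood at 0.12, above 0 in 6 of 6 bulls, with a camera p of 0.241. Camera sets a list against the other genes and not against 0. The median tested gene itself stood at 0.057 for H3K4me2 and at 0.0019 for H3K27me3. A list median above 0 is thus not by itself enrichment relative to other genes. In this list the germ line regulator PRDM14 averaged 0.55 ± 0.63 for H3K4me2 and the oocyte factor GDF9 0.43 ± 0.77. Camera called 0 of 17 lists for either mark, with 0 for H3K4me2 and 1 for H3K27me3 at an unadjusted p under 0.05. The lowest adjusted p for H3K4me2 was 0.832, and adjusted p = 0.854 with an estimated correlation. Over all lists but the single gene TNP1, the mean bull median ranged from -0.11 for leukocyte markers (-0.146 to -0.0331 over 11 alternatives) to 0.16 for the flagellum (0.0026 to 0.211) in H3K4me2. It ranged from -0.18 for testis-specific glycolysis isozymes (-0.293 to 0.00515, so with either sign) to 0.11 for early embryo genes in H3K27me3. The median gene value, the mean gene value and the test differed in sign for developmental signalling, developmental transcription factors, imprinted, leukocyte, housekeeping, ribosomal, somatic testis and steroid genes in H3K4me2, and for imprinted, leukocyte, ribosomal and flagellum genes in H3K27me3.

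The marks were compared within bulls to ask which genes carried relatively more of one of them. Genes chosen after their values were seen, for the smallest p with the bull as a replicate block and one sign in all 6 bulls, included PSMB10, an immunoproteasome subunit, which was higher for H3K4me2 by 1.63 ± 0.64 (log2, mean ± SD over 6 bulls). SCD5, a fatty acid desaturase, was higher for H3K4me2 by 1.32 ± 0.71 and MRE11A, a nuclease of DNA break repair, by 0.90 ± 0.63. ALAS1, the first enzyme of heme synthesis, differed by -1.16 ± 0.70, BCAT1, a transaminase of branched-chain amino acids, by -0.70 ± 0.39, and TLR5, the receptor of flagellin, by -0.65 ± 0.44, with H3K27me3 higher. Limma called 0 of 6805 genes. In the unblocked fit 41 (0.602%) had an unadjusted p under 0.05, 22 higher for H3K4me2 and 19 for H3K27me3. With the bull as a block 283 (4.16%) did, 163 and 120, at a lowest adjusted p of 0.770 for PSMB10. The median gene stood 0.063 log2 units higher for H3K4me2, as arrays were centred on probes and not on genes. The balance of 163 and 120 therefore includes that shift. Chance gives a share of 0.05 in the blocked fit. The unblocked fit took the 2 arrays of a bull as independent, although they correlated. This widened its errors (median standard error 0.366, against 0.231 with the block), so its share cannot be set against 0.05. The unblocked count of 41 was 62 without HF2, 68 without HF3, 66 without SF1, 22 without HF5 and 26 without SF5. Camera, run without the bull as a block, called 0 of 17 lists, and chromatin modifiers had the smallest p, 0.172, at an adjusted p of 0.997. Array position on the slide went with the mark in every bull, so position and mark could not be told apart.

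Within an array, neighbouring probes went together only over short distances. The log2 ratios of probe pairs less than 60 bp apart, which overlap because each probe has 60 bases, correlated with a median r of 0.769 over the 12 arrays, those 60 to 150 bp apart of 0.418, those 150 to 300 bp apart of 0.150 and those more than 300 bp apart, up to 1 kb, of 0.00917. ZNF192, whose 2 probes span 30612110 to 30612203 on chromosome 23, and OXA1L, whose 3 probes span 22340942 to 22341037 on chromosome 10, were therefore each read on a short stretch. So were genes of many probes, such as NGDN (29 probes, 21760311 to 21760547) and EIF3D (38 probes, 80567871 to 80568182). Their probes are not as many independent readings. The probes of KAT7 and PATZ1 span longer stretches, but their spacing within these was not examined. These correlations run across probe pairs, which are not independent replicates.

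**Figure D5:**
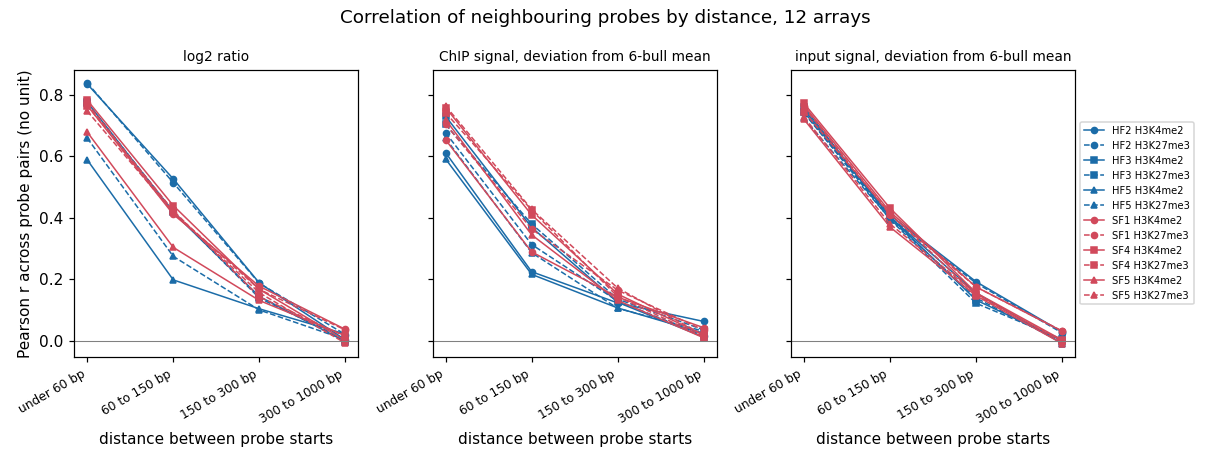
Pearson r (no unit, vertical axes) between probes of one array by the distance between them in bp (horizontal axes), for the log2 ratio, the ChIP signal and the input signal, the signals as deviations from the mean of the 6 bulls, with a line per array, solid for H3K4me2 and dashed for H3K27me3. Median r of the log2 ratio goes from 0.769 at under 60 bp to 0.00917 at distances above 300 bp.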

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

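Chosen only after the data were seen were the alternatives with the GC trend removed, without HF5 and SF5 together, with slide as a random block on all 12 arrays, loess and the deposited table for array agreement, and loess for regions without a symbol. At an adjusted p of 0.05 limma called 0 genes and probes under the 22 gene and 21 probe alternatives run for each fertility comparison, the 18 for each enrichment and the 20 for each comparison of marks, and camera called 0 lists under the 12 run for lists, which left out removal of the GC trend, scaling, quantile normalization, no centring, the stricter probe filter, other moderation and gene medians. Genes at an unadjusted p under 0.05 ranged from 165 to 555 for H3K4me2 and from 235 to 614 for H3K27me3 between fertility groups, with a lowest adjusted p of 0.475 and 0.0686 over the alternatives; probes ranged from 4530 to 14613 and from 5641 to 15370 (lowest 0.535 and 0.409). Enrichment ranged from 107 to 492 and from 147 to 479 genes (0.528 and 0.119), the difference between marks from 15 to 283 (0.962) and the mark comparison from 22 to 283 (0.770), the highest with the bull as a block in the mark comparison, and with that block and the GC trend removed together in the difference between marks, where the block alone gave 268. The highest fertility counts came with slide as a random block on all 12 arrays. That block gave all arrays of a slide 1 correlation, 0.483 for genes. The arrays of HF5 and SF1 on slide 4 did not show it (r from -0.08 to -0.04), so these counts rest on a block that does not hold there. Counting an unadjusted p under 0.05 with a log2 difference of at least 1, in place of an adjusted p, gave 195 and 243 genes and 5295 and 7584 probes for H3K4me2 and H3K27me3; a looser threshold by construction. Of the values of named genes under the alternatives 3179 kept direction and side of the threshold and 13 took the other sign; the cause was not tested. These were SLC25A40 for H3K4me2 between groups with Cy5 alone (0.27); MEG3 (0.50), TNP1 (0.13) and MAEL (0.25) for H3K4me2 within slide 4; TNP1 for H3K4me2 enrichment under loess (0.056), the deposited table (0.061) and the GC trend removed (0.32), with -0.18 to 0.048 when leaving out each bull; and TNP1 for H3K27me3 between groups with the GC trend removed (0.018) and Cy5 alone (0.47), with -0.45 to 0.15 when leaving out each bull. Part of the 3179 was fixed by the naming rule, so this count is not a measure of robustness. Genes named for no overlap of the fertility groups could not change sign without a bull or within slide 4. Genes named for the same sign in every bull could not change it without a bull either. Keeping the side of the threshold meant only that an adjusted p of 0.05 was still not passed. Of the list medians 768 moved by less than the spread between bulls and 24 by more. The planned slide block within 1 mark was not run, because only 1 slide held 2 arrays of a mark. Signal limited HF5 and SF5 most, with 93.9% and 95.7% of H3K4me2 ChIP spots well above background.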

Other observations

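Tests of the same-bull agreement, of the GC trend and of domains longer than 300 bp, and the look at which bulls each split joined, were chosen only after the result was seen; the other splits of the bulls and the test of input fragments were set beforehand. Regions that carry no gene symbol were fitted in the same way: of 10659 such regions 4921 had enough probes, limma called 0 for either mark, and 147 for H3K4me2 and 174 for H3K27me3 had an unadjusted p under 0.05, of which 74 and 88 were higher in high-fertile bulls.

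The 10 splits of 6 bulls into 3 and 3 are too few for a share under 0.05. For H3K4me2 genes the real split gave 198 at an unadjusted p under 0.05 and the highest other 598, with 10 of the 10 splits giving at least 198; for H3K27me3 genes 277 and 440, with 9 of 10. For probes the values were 5295 and 14789 (9 of 10) for H3K4me2 and 7584 and 12595 (10 of 10) for H3K27me3. For the difference between marks they were 45 and 63 (5 of 10), in the fit that took the 2 arrays of a bull as independent. For H3K4me2 the 4 splits that put HF5 and SF5 on one side gave 440 to 598 genes and the other 6, fertility among them, 198 to 259. This points to a structure of the samples that follows these 2 arrays, the ones of lowest ChIP signal for this mark. For H3K27me3 the same 4 splits gave 321 to 440 genes and the others 271 to 412. For the mark comparison with the bull as a block, 10 of 32 ways of swapping the arrays within bulls gave at least 283 genes, the highest other giving 367, so chance cannot be excluded.

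The H3K4me2 and H3K27me3 profiles of one bull went together at a mean r of 0.567 across genes. A shared slide as the source was argued against by the HF5 and SF1 arrays of slide 4, whose highest r was -0.038. Shared input DNA may account for part or most of it. With ChIP signals set against the mean input of the 6 bulls the mean same-bull r was 0.297, with a median of 0.139 for different bulls and marks. Over each bull's own input that median was 0.0036, so the same-bull excess fell further than 0.567 and 0.297 alone show. Different bulls of the same mark had a mean r of 0.145 over the mean input. HF2 (0.46), HF5 (0.38) and SF1 (0.47) lay well above the median of 0.139, and HF3 (0.18), SF4 (0.19) and SF5 (0.10) near it. The exact one-sided permutation p of that same-bull value was 0.00278 among 720 pairings. The bull's own chromatin stays open and cannot be told apart from how its samples were handled, since each bull has 1 array per mark.

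The H3K4me2 arrays of HF5 and SF5 favoured GC-rich probes by 0.90 and 1.02 log2 units, and their H3K27me3 arrays by 0.65 and 0.22. A gap of that size was not seen in the other 4 H3K4me2 arrays, whose highest was 0.12, and 0.21 after loess (0.01 in SF4, 0.15 in HF2, 0.19 in SF1). These 4 arrays correlated with each other across genes only at r from -0.0092 to 0.046. They may therefore hold too little shared signal of the mark to decide whether H3K4me2 is enriched at GC-rich sequence, which stays open. A candidate explanation is a ratio that depends on brightness at low ChIP signal. After loess within the array the larger gap of the 2 was 0.11. This cannot decide the question, because loess removes any trend of the ratio with brightness, whatever its source. It also moved the gap of the HF3 H3K4me2 array, of higher ChIP signal, from -0.24 to 0.21. A low ChIP signal does not set the size of the gap by itself, since the H3K27me3 array of SF5 had a median of 530 and a gap of 0.22. No biological explanation by fertility group was tested, as the 2 bulls belong to different groups.

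Probes near each other went together only over short distances, and no fragment length was measured. Domains of a mark longer than 300 bp that differ between bulls were argued against as the source of a large share of the variation. The highest r of ChIP deviations more than 300 bp apart over the 12 arrays was 0.0629. This r pools all probe pairs of an array, so it cannot exclude such domains at a small share of the regions. Uneven recovery or amplification of DNA fragments may account for the pattern, because the input signals alone, which carry no mark, had a median r of 0.403 at 60 to 150 bp. No biological explanation other than such domains was tested.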
